A study of Homo sapiens with 6 samples.

How the data were processed

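RNA was sequenced from HaCaT cells, an established line of immortalised human keratinocytes. The series holds 6 libraries in 2 groups, 3 kept for 24 h with interferon beta (IFN-beta) at 160 ng/mL and 3 control libraries kept as long in the same serum-free medium without it. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The batch of each library is given as unknown in the labels.

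The authors deposited 1 table of FPKM values (fragments scaled by gene length and library depth) for 60671 genes, with Ensembl identifiers, symbols, gene coordinates and pathway and ontology terms per gene. Per the labels' protocols, libraries were built from total RNA taken with an RNeasy kit, while the treatment protocol names TRIzol, and the protocol lists CLC Genomics Workbench 11.0.1 without saying for which step. The aligner, the counting program and its use of strand are not given in the sources used here. Per the submitters' processing notes the genome builds were GRCm38 and mm10, which are mouse builds. The table goes against those notes: 60671 of its 60671 identifiers are human. Of the 58453 identifiers also held by GENCODE release 29 (human build GRCh38), 45038, or 77.05%, had the same chromosome, start and end there, so coordinates are printed as the deposited table gives them, with the build inferred and not stated. The value columns were matched to the samples by name, and all of them were used.

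The depth behind the FPKM was recovered from its steps. For each library a whole total was found, and for each gene the smallest whole length that turned its 6 values into whole reads within 0.01 reads. This succeeded for 100% of the 30507 genes with a value above 0, and the recovered reads summed to between 99.72% and 99.73% of the totals. The totals ran from 25832158 to 30594527 reads. In genes with few reads the true count may be a multiple of the recovered one. Reads are not independent molecules, so a floor set by reads covers counting error only. The floor for a gene at or near 0 was 3 reads.

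Values were tested as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided), over the 15163 genes with a mean FPKM of at least 0.5 across the 6 libraries. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes at low levels. FPKM are not counts, so no count model was the main test. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

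Before the data were examined, 25 gene lists, the tests, most alternatives and the rule for naming genes were fixed. Lists with at least 5 tested genes, 22 in number, were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated per list, and with limma's fry, with adjustment over the lists. With an estimated correlation camera also has far fewer degrees of freedom, set by the libraries and not by the genes. Enrichment of the deposited GO, KEGG and Reactome terms was tested per direction with a one-sided Fisher exact test over the 4747 terms with 10 to 500 tested genes, against the 11800 tested genes that carry a term. Named are the 12 called genes with the largest rise and the 12 with the largest fall whose groups did not overlap and whose 3 values in the higher group were at least 1 FPKM, up to 4 called members of each list by size of change, up to 2 members that did not pass by level, and a fixed set, among them STAT2, IRF9, IFNAR1, IFNAR2, IFNB1, PIEZO1, STING1, CGAS, CORT, AGER, GLO1, KRT5, KRT14, KRT10, MKI67, GAPDH and ACTB. Some genes that the rule covers are not reported here. Some members that went against the rest of their list are named as well, as is the lowest gene of the antiviral list, and those outside the rule were chosen after their values were seen.

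The alternatives were pseudocounts of 0.1 and 1, no filter on low values, a minimum mean FPKM of 2, rescaling to the same sum (TPM), quantile normalization, median-of-ratios size factors, eBayes without the trend and with robust fitting, the replicate number as a block, each library left out in turn, and terms of 20 to 300 genes. Added after seeing the data were limma voom on the recovered reads, rescaling without the mitochondrially encoded genes, only the genes that GENCODE release 29 types as protein coding, and removal of each library's trend on gene length and GC content. The fits were checked on simulated data for this comparison over 15007 genes. Of 50 genes changed 1.25-fold, 56% were called, and 86% at 1.5-fold, 92% at 2-fold and 100% at 4-fold. Among 14782 unchanged genes 11 were called, and 3 of 200 unchanged lists had an unadjusted camera p under 0.05. The simulated noise was independent between genes and few genes were changed. These error rates therefore do not carry over to lists of correlated genes or to data with many changed genes.

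Replicates of a group were compared before they were averaged. Their recovered reads differed by a chi-square of between 3.01 and 10.2 per gene, so no library repeated another. Where genes share exonic bases on the same strand, the counted level can be too low: IRF9 shares 48.4% of its exonic bases, IFNAR2 44.2%, IL10RB 38.1% and TREX1 100%, and TREX1 had 0 reads in all libraries. If the counting ignored strand, overlap on either strand matters, with 83.2% for IFNAR2, 38.3% for XAF1 and 20.2% for PIEZO1. HLA genes, histone genes, ribosomal protein genes and BCYRN1 have near-identical copies elsewhere in the genome, between which the authors' counting could have split reads, so their levels are uncertain.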

Results

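The transcriptome of HaCaT keratinocytes was measured after 24 h in serum-free medium with IFN-beta at 160 ng/mL (n = 3 libraries) or without it (n = 3 libraries). IFN-beta is a type I interferon, a secreted protein that signals through the IFNAR1 and IFNAR2 receptor chains. Values are FPKM as deposited by the authors, with errors between libraries given as SD (n = 3 per group) and errors of log2 changes as SE. The libraries held between 25832158 and 30594527 reads, and between 23262 and 24806 genes had a value above 0. Across the 15163 genes tested, log2 values of libraries of the same group correlated with r between 0.9938 and 0.9951 and those of different groups with r between 0.9732 and 0.9759. Genes are not independent replicates in these correlations. The first principal component held 74.3% of the variance and separated the groups.

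The comparison addresses how keratinocytes respond to a type I interferon. The strongest rises were in antiviral effector genes. MX1, a GTPase that blocks the replication of RNA viruses, went from 4.57 ± 0.204 to 680 ± 15.7 FPKM, a log2 change of 7.07 ± 0.043 (limma adjusted p = 1.58e-12). Its paralog MX2 rose by 8.61 on the log2 scale, IFI27 by 8.42, IFI44L by 8.29, BST2, which tethers budding virions to the cell surface, by 7.85, and IFI6 by 7.45. The chemokines CXCL10 (7.20) and CXCL11 (6.10), the radical SAM enzyme RSAD2 (6.06), XAF1 (5.63), the oligoadenylate synthetase OAS2 (5.63) and the nucleotide kinase CMPK2 (5.53) completed the 12 largest rises. In the control libraries MX2 stood at 0.264 ± 0.139 FPKM and IFI44L at 0.249 ± 0.131 FPKM, near the pseudocount, so their log2 changes understate the ratio of FPKM.

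Falls were smaller. The long noncoding RNA DANCR went from 15.4 ± 0.859 to 4.19 ± 0.508 FPKM, a log2 change of -1.76 ± 0.088 (limma adjusted p = 1.02e-06). ACO1, the cytosolic aconitase that also acts as an iron regulatory protein, had a log2 change of -1.71, and the keratins KRT13 and KRT15 had changes of -1.55 and -1.29. KRT13 went from 290 ± 56.2 to 97.5 ± 1.42 FPKM and KRT15 from 398 ± 77.1 to 160 ± 2.30 FPKM. The remaining genes among the 12 largest falls were the noncoding RNAs AP002360.1 (-1.74), LINC02562 (-1.34) and BCYRN1 (-1.45), the processed pseudogene AL031729.1 (-1.70), the lysine methyltransferase ATPSCKMT (-1.37), the cytochrome P450 CYP1B1 (-1.34), the metallophosphoesterase MPPED2 (-1.34) and the integrin ITGAE (-1.27). AL031729.1 rested on 3 to 40 reads per library, and BCYRN1 and this pseudogene have near-identical copies elsewhere, so their levels are uncertain.

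In all, 6431 of the 15163 genes tested, or 42.4%, passed the limma test, of which 3419 were higher and 3012 lower with IFN-beta. A change of at least 2-fold was called in 501 genes, with 449 higher and 52 lower, and 122 genes rose at least 4-fold and 27 at least 16-fold. The groups did not overlap in 8182 genes, or 54%, where chance gives 10%. Higher genes made up 53.2% of the calls, against 63.2% after rescaling to the same sum and 41.3% after quantile normalization, so the balance of many small changes depends on the scaling.

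All 57 antiviral interferon-stimulated genes were tested and all 57 rose, by a median of 3.18 on the log2 scale, and 57 were called when adjusted over the list alone. Their share of all reads went from 0.387% ± 0.0013 to 2.96% ± 0.055 (n = 3 each, two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries can give). The list differed from the other genes (limma camera adjusted p = 8.50e-48, and adjusted p = 0.0336 with an estimated correlation). At the low end of the list stood TRIM14, with a log2 change of 1.00.

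**Figure D1:**
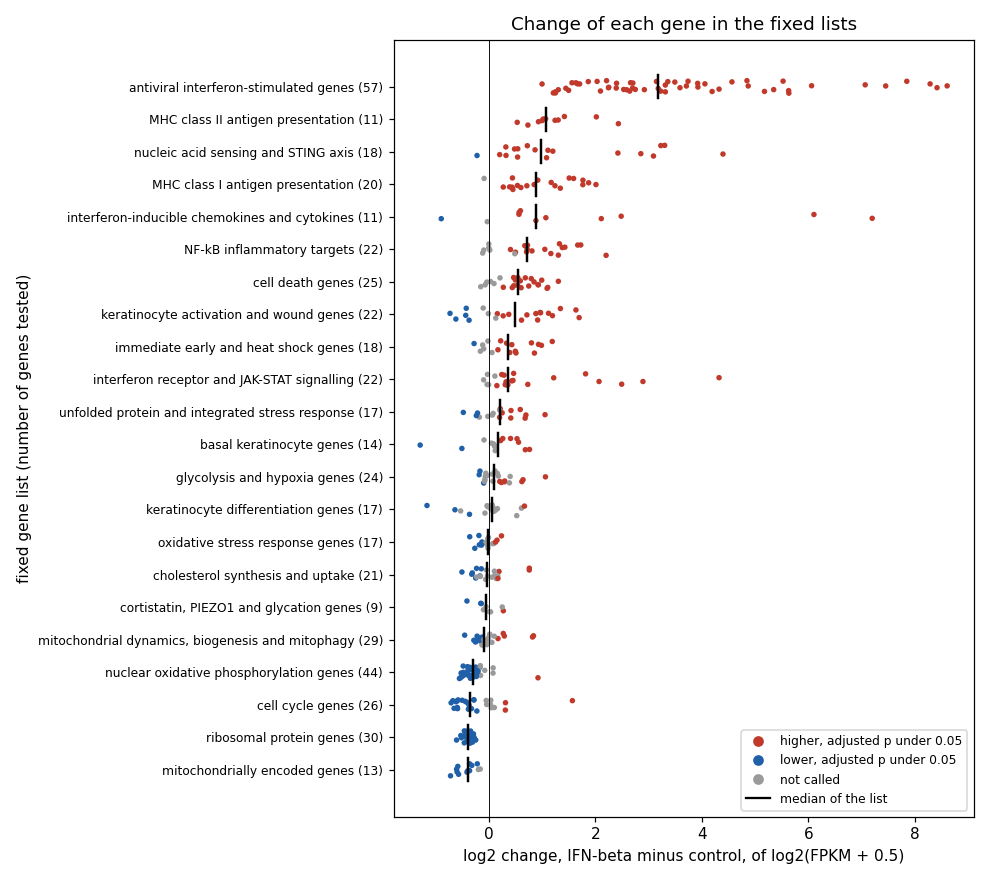
Log2 change (IFN-beta minus control, of log2(FPKM + 0.5), horizontal axis) of each tested gene in the 22 gene lists with at least 5 tested genes (vertical axis), as 1 point per gene, with black bars at list medians. Red and blue points passed the limma test as higher and lower, and grey points did not; the antiviral list has a median of 3.18 and the ribosomal protein list, all of it below 0, a median of -0.40.

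Most listed genes that carry interferon signals rose as well. STAT2 went from 14.9 ± 0.973 to 85.9 ± 3.01 FPKM (log2 change 2.49 ± 0.055). USP18, a protease that restrains receptor signalling and is also on the antiviral list, had a log2 change of 4.32, and STAT5A had one of 2.07 from a control level of 0.477 ± 0.116 FPKM. IRF9, the DNA-binding partner of STAT2, had a log2 change of 1.82 ± 0.142, at a level that is uncertain because 48.4% of its exonic bases are shared with another gene. Of 22 tested genes of the interferon receptor and JAK-STAT list 17 rose, and 17 were called when adjusted over the list alone (limma camera adjusted p = 1.07e-06, and adjusted p = 0.118 with an estimated correlation). The receptor gene IFNAR1 stood at 31.0 ± 1.39 and 30.4 ± 0.588 FPKM (log2 change -0.03, limma adjusted p = 0.659), and turned to 0.02 after rescaling to the same sum. Its change ran from -0.07 to -0.01 when single libraries were left out and was -0.08 after quantile normalization. IFNAR2 went from 2.64 ± 0.0966 to 3.44 ± 0.380 FPKM (0.32 ± 0.10, limma adjusted p = 0.0308), a level also uncertain from shared exons. Its call ended without control replicate 1, 2 or 3 (limma adjusted p = 0.0558, 0.0890 and 0.0505) and without IFN-beta replicate 1 or 3 (limma adjusted p = 0.0673 and 0.109). It also ended without the filter on level (limma adjusted p = 0.0867) and after quantile normalization (log2 change 0.21, limma adjusted p = 0.125).

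Sensors of foreign and displaced nucleic acids were higher. STING1, the adaptor that cyclic dinucleotides activate, lies on chromosome 5 from 139475533 to 139482935 and went from 9.66 ± 0.427 to 18.0 ± 0.473 FPKM (log2 change 0.87 ± 0.056, limma adjusted p = 5.28e-06). CGAS, the DNA sensor that makes the cyclic dinucleotide, went from 11.0 ± 0.245 to 18.5 ± 0.436 FPKM (0.72 ± 0.051). The list of nucleic acid sensing and STING genes had 18 tested members, of which 17 rose, and 18 were called when adjusted over the list alone (limma camera adjusted p = 7.70e-11, and adjusted p = 0.0336 with an estimated correlation). The list median was 0.97, or 0.63 without the filter on level. The transcription factor IRF7 (4.40), the DNA sensor AIM2 (3.30) and the RNA sensors IFIH1 (3.23) and DHX58 (3.09) had the largest log2 changes. The member that fell was MAVS, the mitochondrial adaptor of the RNA sensors, with a log2 change of -0.22. The MAVS call ended without control replicate 1 or 2 (limma adjusted p = 0.0556 and 0.0598) and without IFN-beta replicate 1 or 2 (limma adjusted p = 0.0724 and 0.0615). It also ended without the filter on level (limma adjusted p = 0.0536) and after rescaling to the same sum (0.0573).

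Antigen presentation genes rose in both classes. Among the 20 tested MHC class I genes 19 rose, led by HLA-F (2.01), the peptide transporter TAP1 (1.87), HLA-B (1.77) and the class I transactivator NLRC5 (1.76), and 19 were called when adjusted over the list alone (limma camera adjusted p = 1.58e-11, and adjusted p = 0.120 with an estimated correlation). The chaperone CANX had a log2 change of -0.09 and did not pass, with 0.06 after quantile normalization, -0.06 without IFN-beta replicate 3, -0.045 after rescaling to the same sum and -0.048 with the length and GC trend removed. All 11 tested MHC class II genes rose, with CTSS, the cathepsin that trims the invariant chain, at 2.43, the invariant chain CD74 at 2.02, HLA-DPA1 at 1.42 and HLA-DRA at 1.30, and 11 were called when adjusted over the list alone (limma camera adjusted p = 5.82e-08, and adjusted p = 0.118 with an estimated correlation). CD74 went from 37.2 ± 4.96 to 152 ± 15.3 FPKM. HLA genes resemble each other, so their single levels are uncertain.

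Secreted and surface signals changed. Of 11 tested interferon-inducible chemokines and cytokines 9 rose, among them the death ligand TNFSF10 (2.48) and the checkpoint ligand CD274 (2.11), and 10 were called when adjusted over the list alone (limma camera adjusted p = 2.35e-05, and adjusted p = 0.118 with an estimated correlation). The monocyte attractant CCL2 fell from 74.7 ± 2.36 to 39.9 ± 0.646 FPKM (log2 change -0.90 ± 0.040). IL15 had a log2 change of -0.03 and did not pass. Among 22 tested NF-kB inflammatory targets 16 rose, and 17 were called when adjusted over the list alone (limma camera adjusted p = 5.17e-07, and adjusted p = 0.0336 with an estimated correlation). IL6 went from 1.25 ± 0.228 to 7.52 ± 0.462 FPKM (log2 change 2.20), IL1A had a change of 1.72, the chemokine CCL20 one of 1.67 and the epidermal cytokine IL36G one of 1.43.

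PIEZO1, a mechanically gated cation channel, was measured at 127 ± 8.69 FPKM in control and 153 ± 6.48 FPKM in IFN-beta libraries (log2 change 0.27 ± 0.055, limma adjusted p = 0.0040). The table places it on chromosome 16 from 88715338 to 88785220. Of the exonic bases of PIEZO1 20.2% are shared on the opposite strand, which matters if the counting ignored strand. Cortistatin transcripts (CORT) were not detectable at this depth, with 2, 2 and 0 reads in the control and 2, 0 and 1 reads in the IFN-beta libraries, where 3 reads correspond to 0.115 FPKM, and 46.5% of the exonic bases of CORT are shared with another gene. AGER, the receptor for advanced glycation end products, stood at 1.44 ± 0.308 and 1.79 ± 0.155 FPKM (0.25 ± 0.146, limma adjusted p = 0.20), a change that shrank to 0.12 without control replicate 3 and to 0.135 after quantile normalization. Of the 21 genes listed for cortistatin, PIEZO1 and glycation 9 were tested, 4 passed the test and 4 when adjusted over the list alone, and the list as a whole did not stand apart (limma camera adjusted p = 0.347, and adjusted p = 0.530 with an estimated correlation). The deglycase PARK7 had a log2 change of -0.41, GLO1, which detoxifies methylglyoxal, one of -0.16 and LGALS3 one of -0.14. The GLO1 call ended without control replicate 2 (limma adjusted p = 0.0599) and without IFN-beta replicate 1, 2 or 3 (limma adjusted p = 0.0503, 0.0742 and 0.0747), and that of LGALS3 without control replicate 2 or 3 (limma adjusted p = 0.131 and 0.0569) and without IFN-beta replicate 1, 2 or 3 (limma adjusted p = 0.122, 0.0754 and 0.0629). Both calls also ended without the filter on level (limma adjusted p = 0.0611 for GLO1 and 0.0829 for LGALS3), after rescaling to the same sum (0.0743 and 0.120) and in the eBayes fit without trend (0.0724 and 0.0921). That of LGALS3 ended after rescaling without mitochondrially encoded genes as well (limma adjusted p = 0.0511).

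Mitochondrially encoded transcripts were lower. Reads from the mitochondrial chromosome made up 6.41% ± 0.249 of reads in control and 4.72% ± 0.254 in IFN-beta libraries (n = 3 each, two-sided exact permutation p = 0.1, the smallest possible). Of the 13 mitochondrial protein genes 11 fell, and 12 were called when adjusted over the list alone, with a median log2 change of -0.40 (limma camera adjusted p = 6.02e-06, and adjusted p = 0.259 with an estimated correlation). MT-CO3 went from 9051 ± 295 to 5491 ± 321 FPKM (log2 change -0.72 ± 0.058), MT-ATP8 had a change of -0.61, MT-CYB of -0.60 and MT-ATP6 of -0.59. MT-CO2, with 9811 ± 103 and 8772 ± 642 FPKM, had a change of -0.16 (limma adjusted p = 0.0622) and MT-ND1 one of -0.20 (limma adjusted p = 0.104). MT-CO2 passed without IFN-beta replicate 1 (limma adjusted p = 0.0353), among genes with a mean FPKM of at least 2 (0.0432), with robust eBayes (0.0295) and with the replicate number as a block (0.0437). It also passed on protein-coding genes alone (limma adjusted p = 0.0369). With limma voom on the recovered reads both MT-CO2 (adjusted p = 0.0053) and MT-ND1 (0.0238) passed. After quantile normalization the list's median was -0.14 and its call ended (limma camera adjusted p = 0.156), as did that of MT-CO3 (log2 change -0.08, limma adjusted p = 0.334). There MT-CYB shrank to -0.34, MT-ATP6 to -0.27, MT-ND1 to -0.03 and MT-CO2 to 0.00, and the highest of the 13 changes was 0.03. Of the 13 genes, 2 held the same rank in every library, which sets their change to 0 under quantile normalization by construction. MT-ND1 also shrank to -0.12 without control replicate 2 and to -0.11 without IFN-beta replicate 2, and MT-CO2 to -0.075 with the length and GC trend removed.

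Nuclear genes of oxidative phosphorylation were lower too. In this list 37 of 44 genes fell, 40 were called when adjusted over the list alone, and the median log2 change was -0.30 (limma camera adjusted p = 2.06e-10, and adjusted p = 0.175 with an estimated correlation). The complex III subunit UQCRB went from 141 ± 11.1 to 95.4 ± 2.22 FPKM (log2 change -0.56), and the ATP synthase subunit ATP5MC1 (-0.53) and the cytochrome oxidase subunit COX6C (-0.52) followed. NDUFV2 alone rose among the 44 genes, from 1.15 ± 0.262 to 2.62 ± 0.471 FPKM, with 28.4% of its exonic bases shared on the same strand. Every one of the 30 ribosomal protein genes fell, by a median of -0.40 with a range of -0.61 to -0.25, and 30 were called when adjusted over the list alone (limma camera adjusted p = 9.67e-13, and adjusted p = 0.243 with an estimated correlation). RPLP0 went from 2227 ± 103 to 1460 ± 39.6 FPKM (log2 change -0.61 ± 0.047), RPS6 had a change of -0.53 and RPL5 of -0.52. After quantile normalization the median of the ribosomal protein list shrank to -0.25 and the change of RPLP0 to -0.40. Genes of mitochondrial dynamics, biogenesis and mitophagy moved both ways, with 16 of 29 called (5 higher and 11 lower) and 17 when adjusted over the list alone (limma camera adjusted p = 0.123, which became 0.0326 without the filter on level, and adjusted p = 0.241 with an estimated correlation). The mitophagy receptors OPTN (0.84) and BNIP3 (0.82) and the autophagy gene MAP1LC3B (0.29) were higher, and the mitochondrial protease OMA1 (-0.46) was lower.

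**Figure D2:**
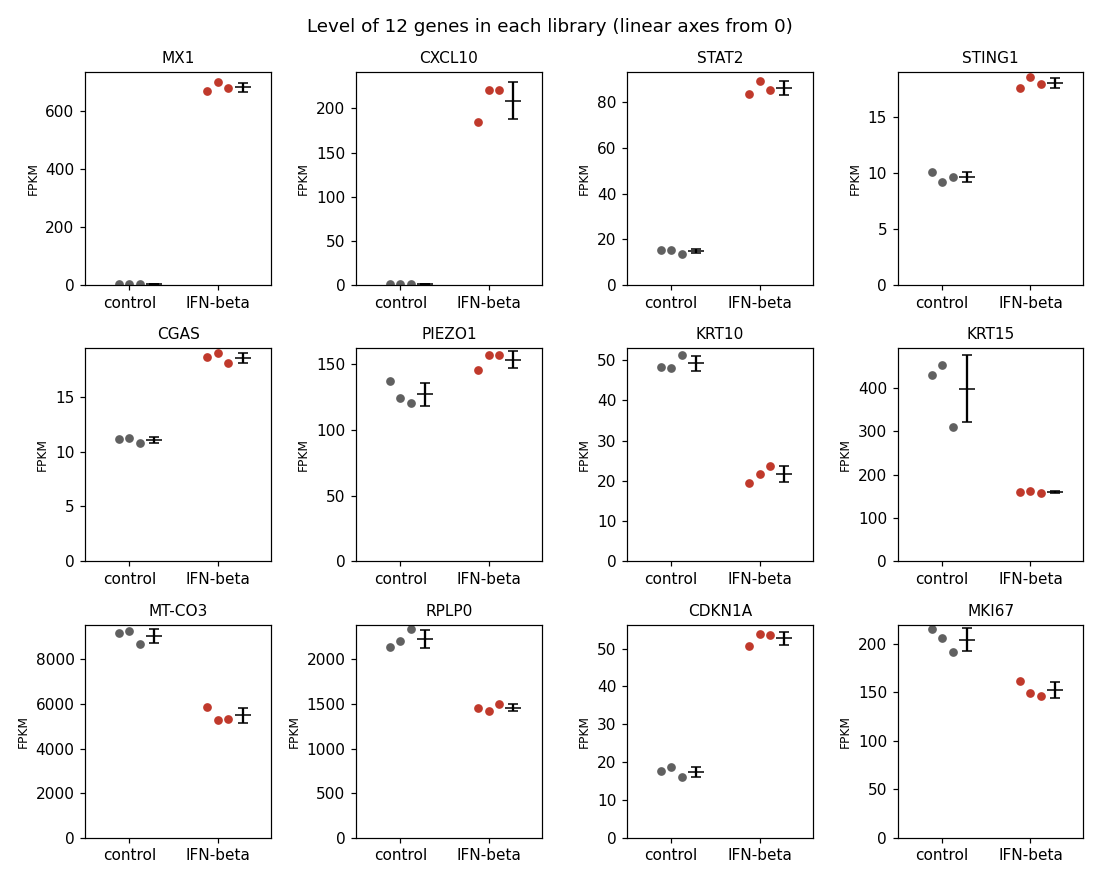
FPKM (vertical axes, linear from 0) of 12 genes in the 3 control (grey) and 3 IFN-beta (red) libraries, with 1 point per library and black bars at the mean with 1 SD. MX1 and STAT2 stand far above their control values, STING1 reaches 18.0 ± 0.473 FPKM, and RPLP0, KRT10 and MT-CO3 lie below their control values in every IFN-beta library.

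Keratinocyte identity genes split. KRT5 fell from 1374 ± 81.0 to 965 ± 14.8 FPKM (log2 change -0.51 ± 0.048, limma adjusted p = 6.04e-05), while its partner KRT14 stood at 1033 ± 42.8 and 1099 ± 32.2 FPKM (0.09, limma adjusted p = 0.137). KRT14 passed after rescaling to the same sum (0.14) and after quantile normalization (0.28). Quantile normalization shrank the change of KRT5 to -0.31, and without control replicate 3 that of KRT14 shrank to 0.06. Among the 14 basal keratinocyte genes 9 were called, and 9 when adjusted over the list alone, with KRT15 and KRT5 lower and the laminin chain LAMA3 (0.76) and the integrin ITGA3 (0.56) among those that rose (limma camera adjusted p = 0.0704, and adjusted p = 0.508 with an estimated correlation). The basal list passed without control replicate 1 (limma camera adjusted p = 0.0499), after quantile normalization (0.0115), without the filter on level (0.0259) and with limma voom on the recovered reads (0.0246). In the differentiation list 17 of 30 genes were tested, 4 were called and 4 when adjusted over the list alone (limma camera adjusted p = 0.622, and adjusted p = 0.731 with an estimated correlation), and its median of 0.06 differed in sign from its mean of -0.03 and the test. The median turned to -0.034 without control replicate 3 and to -0.026 after quantile normalization, and also fell below 0 with the length and GC trend removed. KRT10, a keratin of suprabasal cells, fell from 49.2 ± 1.84 to 21.7 ± 2.09 FPKM (-1.16 ± 0.068), and the proteases KLK5 (-0.64) and KLK7 (-0.37) were lower, while the cross-linking enzyme TGM1 was higher (0.67). The KLK7 call ended without control replicate 1 or 2 (limma adjusted p = 0.0775 and 0.0940) and without IFN-beta replicate 2 or 3 (limma adjusted p = 0.0806 and 0.0774). It also ended without the filter on level (limma adjusted p = 0.0827) and in the eBayes fit without trend (0.0552).

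Genes of keratinocyte activation and wound repair were mostly higher. Of 22 tested members 14 rose, and 19 were called when adjusted over the list alone (limma camera adjusted p = 0.0049, and adjusted p = 0.280 with an estimated correlation). The EGF receptor ligands HBEGF (1.69), EREG (1.34) and AREG (1.19) and the metalloprotease MMP3 (1.63) had the largest log2 changes. With limma voom on the recovered reads the change of MMP3 was 2.61. HBEGF went from 17.7 ± 0.518 to 58.4 ± 3.06 FPKM. The alarmins S100A8 (-0.73), S100A7 (-0.44) and S100A9 (-0.43), the matrix protein TNC (-0.62) and the integrin ITGAV (-0.37) fell.

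Of the 26 cell cycle genes 17 fell and 3 rose. MKI67, a marker of proliferating cells, went from 204 ± 11.7 to 152 ± 8.06 FPKM (log2 change -0.42 ± 0.053, limma adjusted p = 0.000325), CENPF had a change of -0.71, cyclin B1 (CCNB1) one of -0.68 and CDC20 one of -0.66. In this list 20 genes were called when adjusted over the list alone (limma camera adjusted p = 2.63e-05, and adjusted p = 0.118 with an estimated correlation). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 17.5 ± 1.30 to 52.7 ± 1.67 FPKM (1.57 ± 0.059), and RRM2 and CCNE2 both had a change of 0.31. Of 25 tested cell death genes 19 rose, and 21 were called when adjusted over the list alone, 20 higher and 1 lower (limma camera adjusted p = 5.82e-08, and adjusted p = 0.0928 with an estimated correlation). These genes act in opposed directions: CFLAR (1.30) blocks caspase 8, whereas CASP10 (1.10), CASP1 (1.09) and BBC3 (0.99) promote cell death.

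Stress response and metabolic genes moved both ways. In the unfolded protein and integrated stress response list 9 of 17 genes rose, with ATF3 at 1.05 and DDIT3 at 0.69, while DDIT4 (-0.48), PSAT1 (-0.24) and PHGDH (-0.22) fell, and 12 were called when adjusted over the list alone (limma camera adjusted p = 0.0474, and adjusted p = 0.409 with an estimated correlation). The call of this list ended without control replicate 3 (limma camera adjusted p = 0.0867) and without IFN-beta replicate 1 or 3 (limma camera adjusted p = 0.0502 and 0.0713). It also ended with median-of-ratios size factors (limma camera adjusted p = 0.0508), with the replicate number as a block (0.0899) and on protein-coding genes alone (0.0652). Among the 18 immediate early and heat shock genes 12 rose, led by EGR1 (1.19) and FOS (0.99), HSPE1 fell (-0.28), and 15 were called when adjusted over the list alone, 12 higher and 3 lower (limma camera adjusted p = 0.0126, and adjusted p = 0.175 with an estimated correlation). Genes of cholesterol synthesis and uptake went both ways, with STARD4 (0.76) higher and MVK (-0.51) lower, and 11 of 21 called (4 higher and 7 lower), or 12 when adjusted over the list alone (limma camera adjusted p = 0.414, and adjusted p = 0.532 with an estimated correlation). Of 24 glycolysis and hypoxia genes 10 were called (7 higher and 3 lower), and 10 when adjusted over the list alone, with those that rose including the lactate exporter SLC16A3 (1.06), HK2 (0.64) and PGAM1 (0.29) (limma camera adjusted p = 0.347, and adjusted p = 0.731 with an estimated correlation). In the oxidative stress list 9 of 17 were called (3 higher and 6 lower), and 9 when adjusted over the list alone, with catalase (CAT, -0.36) and GCLC (-0.27) lower and TXNRD1 (0.24) higher (limma camera adjusted p = 0.331, and adjusted p = 0.603 with an estimated correlation).

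Reference genes shifted slightly. GAPDH had a log2 change of -0.18 ± 0.040 (limma adjusted p = 0.0071) and ACTB one of -0.13 ± 0.044 (limma adjusted p = 0.0385), and after quantile normalization these turned to 0.06 and 0.08 and did not pass (limma adjusted p = 0.252 and 0.193). The GAPDH call also ended without the filter on level (limma adjusted p = 0.0701). The ACTB call ended without control replicate 1 or 2 (limma adjusted p = 0.0898 and 0.0772) and without IFN-beta replicate 1, 2 or 3 (limma adjusted p = 0.0973, 0.0931 and 0.124). It also ended without the filter on level (limma adjusted p = 0.187), after rescaling to the same sum with (0.150) or without mitochondrially encoded genes (0.0619) and in the eBayes fit without trend (0.0723).

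Markers of other cell types were low. Of the fibroblast markers 2 of 11 passed the filter on level, of the immune cell markers 1 of 15 and of the melanocyte and endothelial markers 2 of 11, too few for a list test. COL1A1 was at 1.80 ± 0.461 and 2.69 ± 0.401 FPKM (log2 change 0.48, limma adjusted p = 0.0391) and the endothelial cadherin CDH5 at 0.731 ± 0.0847 and 1.97 ± 0.101 FPKM (1.01, limma adjusted p = 0.000273). The COL1A1 call ended without control replicate 2 or 3 (limma adjusted p = 0.0963 and 0.105) and without IFN-beta replicate 1 or 2 (limma adjusted p = 0.0867 and 0.129). It also ended without the filter on level (limma adjusted p = 0.130), after quantile normalization (0.0881) and in the eBayes fit without trend (0.0597). IFNB1 itself had 0, 0 and 0 reads in control and 2, 0 and 1 reads in IFN-beta libraries, below the floor of 3 reads.

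Of the 22 lists tested, 15 were called by camera at the preset correlation and 3 with an estimated correlation, namely the antiviral, nucleic acid sensing and NF-kB lists. By limma's fry, which asks whether a list's genes move one way on balance and compares them with no other genes, the antiviral list had an adjusted p of 3.51e-07 and the ribosomal protein list one of 0.0015. Fry also passed the mitochondrially encoded (adjusted p = 0.0030) and nuclear oxidative phosphorylation lists (0.0012). It passed lists that camera did not call, the basal keratinocyte (0.0054) and mitochondrial dynamics lists (0.0049). The lists that fry did not pass were those of cortistatin, PIEZO1 and glycation (0.0664), keratinocyte differentiation (0.164), cholesterol (0.344), glycolysis (0.159) and oxidative stress (0.117).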

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

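Of the listed genes, 77 lay below the filter on level, 57 of them with a read in any library. In 9 of these every IFN-beta library stood above every control library in FPKM, and in 2 every one stood below (FN3K with 4, 3 and 6 reads against 12, 7 and 6, and COL3A1 with 1, 1 and 0 against 2, 2 and 2 in control libraries), where chance gives 5% of genes in each direction. Read totals over the 3 IFN-beta libraries are given for the 9 genes that stood above, which were not part of the limma test, so the differences have no p-value. The keratinocyte interferon IFNK had 21 reads (11, 7 and 3) against 0, 0 and 0 in control libraries, and the lambda interferon IFNL1 had 10 (5, 3 and 2) against 0, 1 and 1. The chemokines CXCL9 and CX3CL1 had 32 reads (19, 5 and 8) against 0, 0 and 0 and 93 reads (23, 24 and 46) against 3, 3 and 6. The cytokine IL33 had 22 reads (12, 3 and 7) against 0, 1 and 1. The keratin KRT6B, whose reads can be shared with close paralogs, had 95 reads (39, 22 and 34) against 16, 19 and 10, and the lipoprotein receptor VLDLR had 198 (65, 60 and 73) against 28, 17 and 19. The macrophage genes CSF1R and CD68 had 13 reads (7, 2 and 4) against 2, 0 and 1 and 14 reads (4, 3 and 7) against 2, 1 and 1.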

How the results depend on the processing

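Tests with limma voom, without mitochondrially encoded genes, on protein-coding genes and with the length and GC trend removed were chosen after the results were seen; the others were planned. Over all alternatives the count of changed genes ran from 5148 to 6897 (6431 as reported) and that of genes changed at least 2-fold from 351 to 744 (501 as reported), and leaving out single libraries gave 5148 to 6165 and 478 to 524. Enriched annotation terms ran from 513 to 732 (618 as reported). The number of lists called by camera ran from 14 to 17, but fell to 3 with an estimated correlation. The estimate was 0.72 for the ribosomal protein and 0.63 for the mitochondrially encoded list, against the preset 0.01. A higher correlation weakens the test. The NF-kB list, with an estimate of -0.007, also went from an unadjusted limma camera p of 1.88e-07 to 0.0046. Correlation within lists is thus not the whole of the drop. When it estimates the correlation, camera also takes its degrees of freedom from the libraries and not from the number of genes. With 6 libraries this weakens the test for every list. The share of each in the drop was not tested. Of 10 splits of the 6 libraries into groups of 3, 1 (the real one) gave as many changed genes, higher genes, lower genes, genes changed 2-fold, lists and terms, which is too few splits for a share under 0.05; the highest other split gave 0 genes and 0 terms by limma and Fisher tests at the same threshold (at most 273 genes at an unadjusted p under 0.05, against 7661), but 13 lists against the real 15. Each other split sets 2 libraries of one group and 1 of the other against the reverse, so it keeps part of the IFN-beta contrast. The rest of that contrast falls into the spread within each group, which favours 0 genes and 0 terms in advance. These splits therefore give no error rate for the real comparison. For named genes 2683 of 2751 gene and alternative pairs kept their direction and side of the threshold. Many of these genes were named for the size of their change in the same fit, which favours agreement in advance. Over all genes, the alternatives shared between 4997 (without IFN-beta replicate 2) and 6423 (pseudocount 1) of the 6431 calls. After quantile normalization ACTB turned to 0.084, GAPDH to 0.064 and CANX to 0.06; after rescaling to the same sum IFNAR1 turned to 0.017 and IL15 to 0.005, and IL15 ran from -0.11 to 0.084 when single libraries were left out, being above 0 without control replicate 2. Quantile normalization forces 1 distribution on all libraries, and the cause of these turns was not tested. The replicate number does not pair the samples: same-numbered libraries had correlated deviations of -0.05, -0.10 and -0.06, and with it as a block 5817 genes were called (3082 higher, 2735 lower, 503 at least 2-fold), with 14 lists and 637 terms. Voom on the recovered reads called 6874 genes. A count test with other packages was planned for whole reads and was not run. Genes with a mean under 0.5 FPKM were outside the main test, and CORT and IFNB1 stayed at or under the floor of 3 reads in every library, so their change was not detectable at this depth.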

Other observations

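The genes, terms and neighbour pairs in this part were chosen after their values were seen, as were the tests of displaced reads and of differences between the mitochondrial genes; the other tests were fixed before their results were seen. The Fisher tests of terms take genes as independent and do not account for gene length, so their p-values can overstate the evidence. Among the 30 tested genes of the annotation term complement and coagulation cascades 18 rose (one-sided Fisher exact test, adjusted p = 0.0018). The proteases C1S (log2 change 2.91) and C1R (2.75) of the classical pathway rose, C1S from 9.50 ± 0.691 to 74.7 ± 4.68 FPKM, as did the central component C3, from 303 ± 48.3 to 532 ± 28.5 FPKM. Genes of extracellular matrix organization were enriched as well, with 74 of 158 higher (one-sided Fisher exact test, adjusted p = 1.88e-07). Of the 49 tested genes annotated as structural constituents of chromatin 29 rose (one-sided Fisher exact test, adjusted p = 2.35e-05), while 65 of 144 kinetochore genes fell (adjusted p = 4.60e-08). The histone genes H2AW (log2 change 2.18) and H2BU1 (1.95) rose, whereas H2AC11 fell (-0.82). Histone genes resemble each other, so single levels are uncertain.

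Mitochondrial translation genes fell in 46 of 93 cases (one-sided Fisher exact test, adjusted p = 3.87e-07), and intraflagellar transport genes, which build the cilium, in 25 of 45 (adjusted p = 5.10e-05). Shorter genes fell more often in these data, with 43.8% of protein-coding genes under 800 bases lower and 15.6% of those over 3000 bases. Neither term was set against genes of matched length. ACO1 ends 533 bases from the end of DDX58, an RNA sensor on the opposite strand that rose by 2.85 on the log2 scale, while ACO1 had a change of -1.71. INKA1 (-0.52) ends 179 bases from UBA7 (2.44), and VAT1 (-0.45) ends 151 bases from IFI35 (3.74). Over all 15 tested genes that end within 5000 bases of a gene raised at least 4-fold on the opposite strand, 4 were lower and 5 higher, with a median log2 change of 0.11, and STAT3 (0.43), next to STAT5A (2.07), was among those higher.

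Ribosomal protein and nuclear oxidative phosphorylation transcripts fell together, in data where 43.8% of protein-coding genes under 800 bases were lower, against 15.6% of those over 3000 bases. The tables argue against a trend on length and GC content as the whole cause, since the higher of the 2 list medians was still -0.25 after each library's trend was removed. Of 10000 random lists matched on length and level, 0 were as low as either. Those random lists had a median of -0.12 for the ribosomal protein and -0.11 for the oxidative phosphorylation list. Part of each fall thus goes with length and level. The random lists were not matched on GC content or on correlation between genes, so 0 of 10000 overstates the evidence. Reads displaced by induced genes would lower every other gene alike, but the median of all genes was 0.01. A shared change of translation machinery transcripts is a candidate description, since 21 of 29 translation factor and snoRNA host genes fell, with a median of -0.25 (limma camera adjusted p = 2.98e-07, and adjusted p = 0.178 with an estimated correlation, over the 2 lists fixed for these tests). The median was -0.21 with the length and GC trend removed. Such a change would widen the pattern to related genes without giving its cause, and it does not cover the oxidative phosphorylation genes. A difference between library batches stays open, since the labels give the batch as unknown.

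For the lower mitochondrially encoded transcripts, a trend on length and GC content is not the whole cause, since the list median was -0.34 after its removal. Of 10000 random lists matched on length and level, 8 were as low as this list, and the random lists had a median of -0.12. Part of this fall thus goes with length and level too. Here as well the random lists were not matched on GC content or on correlation between genes. One uniform change of all mitochondrial messages, as from a lower share of mitochondria in the RNA, would move the 13 genes alike. Their log2 changes ran from -0.72 to -0.16 and differed between genes by more than the replicates did. The F of the gene by group interaction over the 13 genes was 6.3, and 5.9 with the trend on length and GC content removed. In the other splits of the 6 libraries F was at most 1.6. Those splits leave part of the IFN-beta effect in the spread within groups, which lowers their F. After quantile normalization F was 5.4, but 2 of the 13 genes held 1 rank in all libraries. That normalization fixes their change at 0, so this F does not bear on the question. A change in the handling of single mitochondrial transcripts under IFN-beta may remain, as may one in the preparation of the RNA, and both were not tested.

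The rise of CDKN1A and cell death genes raised the hypothesis of a general rise of p53 targets. In 22 other p53 target genes the median log2 change was 0.067, with an SD of 0.547, and 9 were higher and 6 lower, where 3419 of 15163 genes tested were higher (limma camera adjusted p = 0.317). GDF15, one of the 22, rose by 2.08. Among annotation terms, 28 of 68 genes of the p53 signaling pathway were higher (one-sided Fisher exact test, adjusted p = 0.0419), while 104 of 346 genes of transcriptional regulation by p53 were lower (adjusted p = 0.0066). Since the targets went both ways, these values do not decide whether p53 targets rose in general, and that stays open. HaCaT cells carry mutant p53, as is known of the line. Interferon signalling on CDKN1A itself stays open and was not tested.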
